A study of Drosophila melanogaster with 7 samples.

How the data were processed

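Per the labels, the wing discs were dissociated by 1 protocol, which the bulk sample's label also gives, and the bulk library was a stranded polyA library. Gene counts were analysed as deposited; per the submitters' processing notes, the work before deposit involved BDGP6, Cell Ranger and kallisto. Their roles and versions, the aligner, the counting tool and the strand setting were not given in the sources used here. The deposited counts of the single-cell samples were whole numbers of UMIs per barcode, and the deposited bulk counts were whole numbers per gene. Reads were not used here. The bulk file held some gene names altered by spreadsheet software, which were left as they were.

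Class definitions, tests, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The alternatives without barcodes 1 base apart, without barcodes over 50000 UMIs, without cells with 3 or more roX1 UMIs and without the haemocyte-like cluster were chosen after the data were seen. Barcodes with fewer than 200 genes with a count were dropped, which left 4198 of 4204 barcodes (2, 4 and 0 dropped in Drop-seq replicates 1 and 2 and 10x). Fewer than 200 genes was seen in 1, 0, 1, 2, 2 and 0 barcodes of the 6 libraries. The lowest 10x barcode had 7174 counts, so that file held deep barcodes only. Doublets were not removed in the reported values; Scrublet in scanpy marked 5, 2, 2, 1, 6 and 4 cells of the 6 libraries, and a setting without them is given with the other settings.

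Cells were assigned to classes from marker UMIs alone. The myoblast class needed at least 2 UMIs of 6 myoblast markers and more of these than of the epithelium markers Fas3, grh, crb, shg and bbg; the epithelial class needed 0 myoblast UMIs and at least 1 epithelium UMI. Notum, pouch, posterior and anterior cells had 0 myoblast UMIs, at least 1 UMI of their own markers and 0 of the opposite ones. Free RNA in droplets can give a cell a marker UMI, so class shares depend on depth and on this background. Left out of both main classes were 96, 50 and 147 cells with at least 2 myoblast UMIs that did not outnumber the epithelium UMIs, and 9, 101 and 4 cells with neither marker. The classes held 219, 174 and 1512 myoblasts and 155, 650 and 667 epithelial cells; 28, 159 and 146 notum and 66, 245 and 304 pouch cells; 31, 192 and 271 posterior and 36, 170 and 257 anterior cells.

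Raw counts were summed per biological sample and class, because cells are not replicates. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with the sample as a block and the class as the tested term, after filterByExpr and TMM scaling, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Each adjusted p in the report comes from this model or, for gene lists, from camera in limma 3.58.1. The block is sound because both classes come from the same sample; the correlation of paired sums was 0.653, 0.587 and 0.902 in the myoblast contrast, 0.391, 0.438 and 0.808 in the notum contrast, 0.387, 0.490 and 0.849 in the posterior contrast and 0.693, 0.534 and 0.898 in the ct contrast. Genes with 0 counts in a class were given as at least N-fold against a floor of 3 counts. Intervals for shares and ratios cover counting error only. SE is that of the fitted log2 difference.

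Camera tested 22 fixed gene lists with a preset correlation of 0.01, adjusted over the lists of a contrast. It called 14 of 22, 7 of 22, 6 of 22 and 8 of 20 lists in the 4 contrasts. With an estimated correlation it called 0 in each, with smallest adjusted p of 0.491, 0.584, 0.629 and 0.465. With 3 samples the model left so little to estimate the correlation from that hardly any list could pass. The 0 calls therefore do not decide on any list. The preset calls rest on the assumed 0.01, where 0.635 was estimated for ribosomal protein genes in the myoblast contrast.

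Genes were named by rule: the 12 largest differences in each direction among genes that passed, had the same direction in all samples and had a mean of at least 20 CPM in the higher class, and up to 3 members per list by smallest adjusted p. In the comparisons by size the 10 largest in each direction and up to 4 members per list were named. roX1, roX2 and the genes that head clusters were picked after the values were seen. Positions are those of BDGP6.54.

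CPM for comparisons with bulk used the 17469 genes whose symbols were present in both single-cell and bulk files. Ratios were taken on log2(CPM + 1). The size rule asked for at least 4-fold in the same direction in every sample and at least 50 CPM. List medians were placed among 10000 random lists matched on level, and correlations of marker pairs among 10000 random pairs matched on detection. Transcript lengths were known for 3310 of the 4018 genes at 50 CPM. Clusters were made per sample with scanpy 1.11.5 from 2000 variable genes, 20 components, 15 neighbours and Leiden resolution 1.0, and named only by the fixed markers.

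A check with planted differences measured what the tests can find when each gene varies as the trend for its level gives. Variation of single genes beyond that trend was not simulated, so the percentages can be too high for the real samples. In the myoblast contrast 34.3%, 74.6% and 95.5% of planted 1.5-fold, 2-fold and 4-fold changes were found; in the notum contrast 31.3%, 80.6% and 92.4%; in the posterior contrast 50.7%, 85.1% and 100%; in the ct contrast 29.9%, 70.1% and 83.3%. The size rule found 200 of 200 planted 8-fold changes. These were planted in well-expressed genes with counting noise only and lay above the 4-fold limit. Full recovery was thus fixed in advance and does not measure what the rule finds in the real samples. Other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.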

Results

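Gene expression was measured in wing imaginal discs of wandering larvae labelled female. The wing disc of Drosophila melanogaster is an epithelial sac that forms the adult wing and the dorsal thorax, and it carries a layer of myoblasts that forms the flight muscles. The 7 samples were 5 Drop-seq libraries, 1 10x library and 1 bulk RNA library. Drop-seq replicate 1 was the sum of 3 libraries, each a separate set of cells of the same biological replicate, and Drop-seq replicate 2 was the sum of 2 libraries, so the single-cell data held 3 biological samples. Drop-seq replicate 1 held 548 kept cells and a total count of 4704856. Drop-seq replicate 2 held 1096 kept cells and a total of 7918502, and the 10x sample held 2554 cells and a total of 41684828. The median count per cell was 4537.5, 3199.5 and 10619.5 in these samples. The bulk library had a total count of 41876342 over 11584 genes with a count. The 10x platform and the bulk assay had 1 sample each, so differences from them had no replicate check and no test.

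roX1 and roX2 are X-linked non-coding RNAs of the dosage compensation complex, which works in males. They were singled out after their values were seen. roX1 (X, 3857230 to 3862697, minus strand) was at 333 CPM in Drop-seq replicate 2, 10.2 CPM in Drop-seq replicate 1, 17.8 CPM in the 10x sample and 1.80 CPM in bulk. The bulk value is over the genes shared with the single-cell files, the others over all genes. The roX1 level was 278 and 414 CPM in the 2 libraries of Drop-seq replicate 2. In that replicate 115 cells had 3 or more roX1 UMIs, 10.5% of cells (exact 95% interval 8.74 to 12.5). These cells held 96.2% of the replicate's roX1 UMIs, 95.9% of its roX2 UMIs and 17.6% of all its UMIs. Such cells made up 9.20% of the myoblast class (16 of 174 cells) and 11.1% of the epithelial class (72 of 650 cells). Without a source in those cells, RNA spread evenly by depth would leave 37.4% of cells with no roX1 UMI, and 82.1% had none. In the 10x sample 51 cells (2.00%, 1.49 to 2.62) had 3 or more roX1 UMIs and held 93.8% of its roX1 UMIs. Of these, 7 lay in a cluster of 26 cells with sens and elav (26.9% of it, 11.6 to 47.8), the highest share of the 16 clusters.

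**Figure D1:**
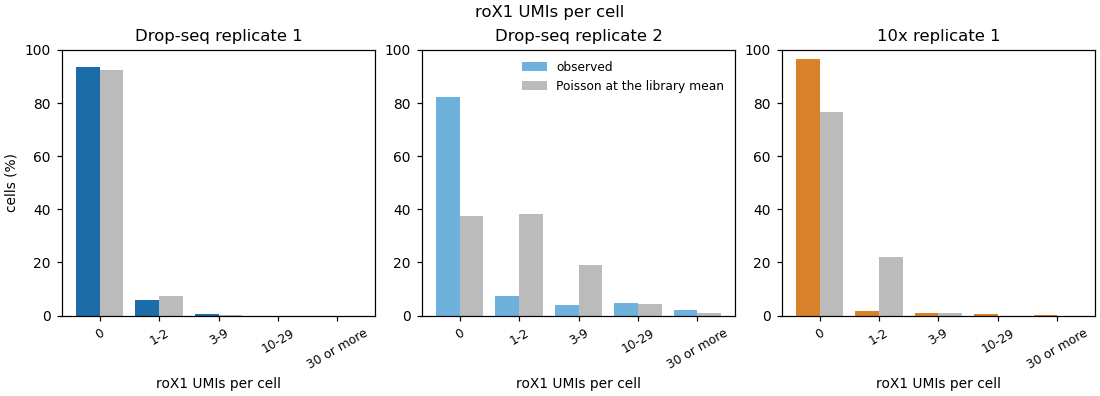
Percent of cells (vertical axis) by number of roX1 UMIs per cell (horizontal axis) in each single-cell sample, beside the percent that even spreading by depth would give (grey). Drop-seq replicate 2 has more cells with no roX1 UMI, and more with many, than even spreading would give.

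The share of cells in the myoblast class was lowest in Drop-seq replicate 2. Cells with at least 2 UMIs of the myoblast markers twi, Him, zfh1, Mef2, htl and stumps, and more of these than of epithelial markers, made up 39.96% of cells in Drop-seq replicate 1 (exact 95% interval 35.8 to 44.2). They made up 15.9% in Drop-seq replicate 2 (13.8 to 18.2) and 59.2% in the 10x sample (57.3 to 61.1). The 3 libraries of Drop-seq replicate 1 had 40.3%, 37.5% and 42.2%, and the 2 libraries of Drop-seq replicate 2 had 19.4% and 12.05%. With every cell thinned to 1000 UMIs the shares were 16.5%, 8.11% and 21.3%, with 4, 184 and 0 cells left out as too shallow. The thinned shares are lower because fewer cells reach the required UMIs, and their order across the samples was the same. The thinned intervals of Drop-seq replicate 1 (13.5 to 19.9) and 10x (19.7 to 22.9) overlapped. That of Drop-seq replicate 2 (6.42 to 10.1) lay below both. Shares in myoblast-like clusters also overlapped between Drop-seq replicate 1 (54.0%, 49.7 to 58.2) and 10x (58.8%, 56.9 to 60.7). No test was made, since 10x had 1 sample. Near the limits of the rule, 69, 121 and 224 cells had 1 myoblast UMI and 65, 50 and 76 cells had 2.

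**Figure D2:**
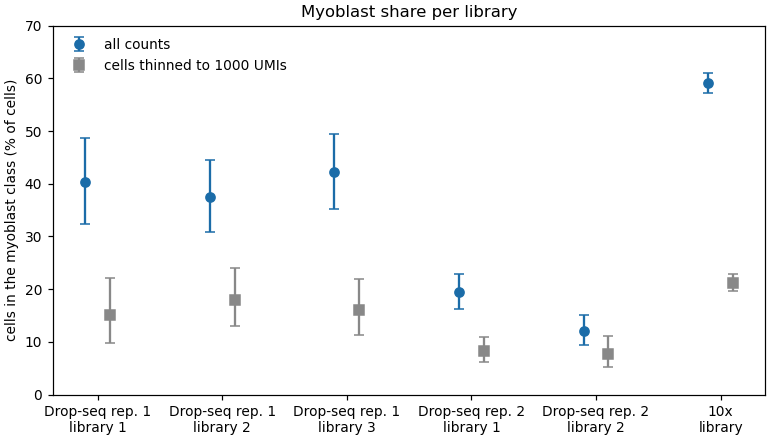
Percent of cells in the myoblast class (vertical axis) in each single-cell library, from all counts and with each cell thinned to 1000 UMIs. Bars are exact 95% binomial intervals for counting error only; both libraries of Drop-seq replicate 2 lie below the other libraries in both settings.

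The contrast of myoblasts with epithelial cells asked which genes separate the main tissue layers of the disc. The largest differences toward myoblasts included single genes of the matrix and of muscle identity. vkg, a collagen IV chain (2L, 5012144 to 5028191), had 314 counts in myoblasts and 0 in epithelial cells, at least 102-fold higher against a floor of 3 counts over the class, and it passed with each sample left out. beat-IIb, of the Beaten path immunoglobulin family, stood at 74.6 ± 11.9 CPM (SD, n = 3) against 0.933 ± 1.35, a log2 difference of 8.17 (SE 0.404, adjusted p = 3.34e-06). lms, a homeobox gene of muscle identity, stood at 34.4 ± 3.11 CPM against 0.205 ± 0.24, a log2 difference of 7.12. BM-40-SPARC, a collagen-binding matrix protein, was at 488 ± 60.8 against 10.8 ± 13.3 CPM, a log2 difference of 6.84. E(spl)m6-BFM, a Bearded family gene, was at 589 ± 139 against 7.98 ± 6.06 CPM, a log2 difference of 6.55 (SE 0.213, adjusted p = 1.37e-06). The other genes with the largest differences toward myoblasts were CG11835, Ef1alpha100E, CG15529, CR45734, CG9593, CR45361 and meso18E, with log2 differences from 6.67 to 7.25. All of these were higher in myoblasts in 3 of 3 samples, as the naming rule required. With 1 sample left out the log2 difference ranged from 6.63 to 9.10 for beat-IIb, 6.30 to 7.68 for lms, 5.83 to 7.56 for BM-40-SPARC, 6.24 to 8.75 for Ef1alpha100E, 6.72 to 7.89 for CG11835, 5.87 to 7.03 for CG15529, 4.67 to 7.34 for CG9593, 4.39 to 7.99 for CR45361 and 5.62 to 7.28 for meso18E, and each still passed.

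The largest differences toward epithelial cells included the following single genes. Brd, the founding Bearded gene (3L, 14972667 to 14973198), was lower in myoblasts by a log2 difference of -6.42 (SE 0.375, adjusted p = 5.54e-06). The proneural gene sc differed by -5.91, E(spl)m4-BFM by -5.93 and the Bearded family gene Ocho by -5.60. The transcription factor genes Doc3, ss and E5 differed by -5.78, -5.73 and -5.57, and the cadherin gene Cad74A by -5.67. CG15282 stood at 335 ± 126 CPM in epithelial cells and 10.7 ± 4.71 in myoblasts. The remaining genes were CG8420, CG8483 and CG13053, with log2 differences of -6.18, -6.14 and -5.65, and CG8420 and CG13053 were not tested without the 10x sample. All of these were lower in myoblasts in 3 of 3 samples, as the naming rule required. Without the 10x sample the log2 difference of sc was -2.64, of E(spl)m4-BFM -2.38, of Doc3 -3.05, of Brd -7.76, of CG8483 -4.89, of ss -4.39, of E5 -4.40, of Ocho -4.16 and of CG15282 -4.47, and each still passed. Without Drop-seq replicate 1 that of E(spl)m4-BFM was -7.24 and that of CG8483 -6.86, and without Drop-seq replicate 2 that of sc was -6.51.

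By gene group, basement membrane and ribosomal protein genes were higher in myoblasts. Of 9 basement membrane and matrix genes tested, 8 were higher and 0 lower, among them trol (perlecan) at 424 ± 260 against 32 ± 29.5 CPM, with a list median of 1.56 (camera adjusted p = 2.45e-06; adjusted p = 0.491 with an estimated correlation). Of 84 ribosomal protein genes, 82 were higher and 0 lower, with a median of 0.49 (adjusted p = 1.86e-30; adjusted p = 0.491 with an estimated correlation), for example RpL36 at 0.62, RpS16 at 0.58 and RpL11 at 0.57. Of 15 mitochondrially encoded genes, 8 were higher and 0 lower, with a median of 0.41 (adjusted p = 0.00197; adjusted p = 0.491 with an estimated correlation), for example mt:CoI at 0.51 and mt:CoII at 0.42. Of 16 DNA replication genes, 5 were higher and 0 lower, with a median of 0.28 (adjusted p = 0.0365; adjusted p = 0.491 with an estimated correlation), for example dpa, an Mcm helicase subunit, at 0.58. With library totals in place of TMM the median of all genes moved to -0.16, and the medians of the ribosomal, mitochondrial and replication lists were 0.31, 0.24 and 0.10. The calls of Mcm7 (0.43) and Mcm5 (0.53), further Mcm subunits, ended without Drop-seq replicate 2 and without the 10x sample, at 0.41 and 0.45 for Mcm7 and 0.53 and 0.37 for Mcm5.

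Most septate junction, Dpp pathway and Wg pathway genes were higher in epithelial cells. Of 13 septate junction genes, 0 were higher in myoblasts and 12 lower, with a median of -2.63 (adjusted p = 8.37e-08; adjusted p = 0.491 with an estimated correlation). The claudins pck and kune differed by -3.46 (SE 0.145, adjusted p = 1.93e-06) and -3.08, and the neurexin Nrx-IV by -2.67. Of 9 apical polarity and adherens junction genes, 6 were lower in myoblasts, with a median of -0.89 (adjusted p = 0.0093; adjusted p = 0.521 with an estimated correlation), for example sdt at -3.17, which was -2.53 without the 10x sample. All 12 Dpp pathway genes were lower, with a median of -1.71 (adjusted p = 1.96e-07; adjusted p = 0.491 with an estimated correlation), among them the inhibitor Dad at -1.94 and the ligand gene gbb at -1.46. Of 9 Wg pathway genes, 8 were lower and 1 higher, with a median of -2.81 (adjusted p = 0.00423; adjusted p = 0.491 with an estimated correlation). Notum and Dll differed by -4.92 and -5.39, or -3.30 and -3.44 without the 10x sample, with Dll at -6.01 without Drop-seq replicate 1, and the Wnt ligand gene Wnt4 was higher in myoblasts by 1.92 (SE 0.172, adjusted p = 4.69e-05). Of 5 Fat and Dachsous genes 4 were lower, with a median of -3.26 (adjusted p = 0.0041; adjusted p = 0.491 with an estimated correlation), for example fj at -2.95 and the atypical cadherin ft at -4.63, which was -3.17 without the 10x sample and -5.30 without Drop-seq replicate 1.

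Further lists with a camera call had most of their passing genes lower in myoblasts. Of 9 EGFR pathway genes 5 were lower in myoblasts and 1 higher (median -0.81, adjusted p = 0.0356; adjusted p = 0.557 with an estimated correlation), for example kek1 at -2.75. Of 7 proximal wing and Iroquois genes 5 were lower (median -1.29, adjusted p = 0.00951; adjusted p = 0.491 with an estimated correlation), for example zfh2 at -3.61, which was -2.89 without the 10x sample and -4.24 without Drop-seq replicate 1. Of 11 Hh pathway genes 5 were lower (median -0.56, adjusted p = 0.0312; adjusted p = 0.491 with an estimated correlation), for example the coreceptor genes boi at -1.86 and ihog at -1.62. Of 12 glycolysis genes 8 were lower and 1, Gapdh1 at 0.94, was higher (median -0.63, adjusted p = 0.0257; adjusted p = 0.582 with an estimated correlation), while the lactate dehydrogenase gene ImpL3, at -2.59, lost its call without the 10x sample, at -1.39. Of 9 immediate early and JNK genes 7 were lower and 1 higher over all genes, or 7 and 2 adjusted over the list alone (median -1.50, adjusted p = 0.0093; adjusted p = 0.491 with an estimated correlation), for example the apoptosis gene hid at -1.96 and the matrix protease gene Mmp1 at -2.98.

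Lists without a camera call held single genes that differed. Of 14 heat shock genes 5 were lower and 1 higher in myoblasts, or 6 and 2 adjusted over the list alone (median -0.10, adjusted p = 0.233), for example the cochaperone gene stv at -3.04, which was -2.43 without the 10x sample. Of 10 E(spl) complex genes 6 were lower and 1 higher (adjusted p = 0.0974), and of 13 muscle differentiation genes 5 were lower and 6 higher (adjusted p = 0.414), among the latter the actin gene Act87E at 6.41, which ranged from 5.28 to 7.61 with 1 sample left out. Of 16 G2/M genes 5 were higher, for example borr at 0.64 and Cdk1 at 0.51 (adjusted p = 0.0974), with a median of 0.14 that turned to -0.03 without TMM. Of 4 JAK/STAT genes, chinmo at 2.08 and Socs36E at 0.58 were higher (adjusted p = 0.128), the latter only with Drop-seq replicate 2 in the fit and at 0.47 without it. Of 11 ecdysone genes 5 were lower and 2 higher, or 5 and 3 adjusted over the list alone (adjusted p = 0.0608), among them ImpE2 at 173 ± 135 against 3430.3 ± 375 CPM. Of 4 direct flight muscle genes 3 were lower and 1, lms, was higher (adjusted p = 0.185). Neither of the 2 histone genes tested passed (adjusted p = 0.734), and members of that family are near-identical copies.

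Over all genes, 2563 of 6618 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1217 higher in myoblasts and 1346 higher in epithelial cells. The higher share was 47.5% with TMM and 31.4% with library totals, where 830 were higher and 1813 lower. The count ranged from 1642 without the 10x sample to 3434 without Drop-seq replicate 1, and it was 1749 without Drop-seq replicate 2. With the sample as a block, the p-values of all class contrasts measured only how the class difference varied over these 3 samples. The samples include both platforms, and their differences in level did not enter the p-values.

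**Figure D3:**
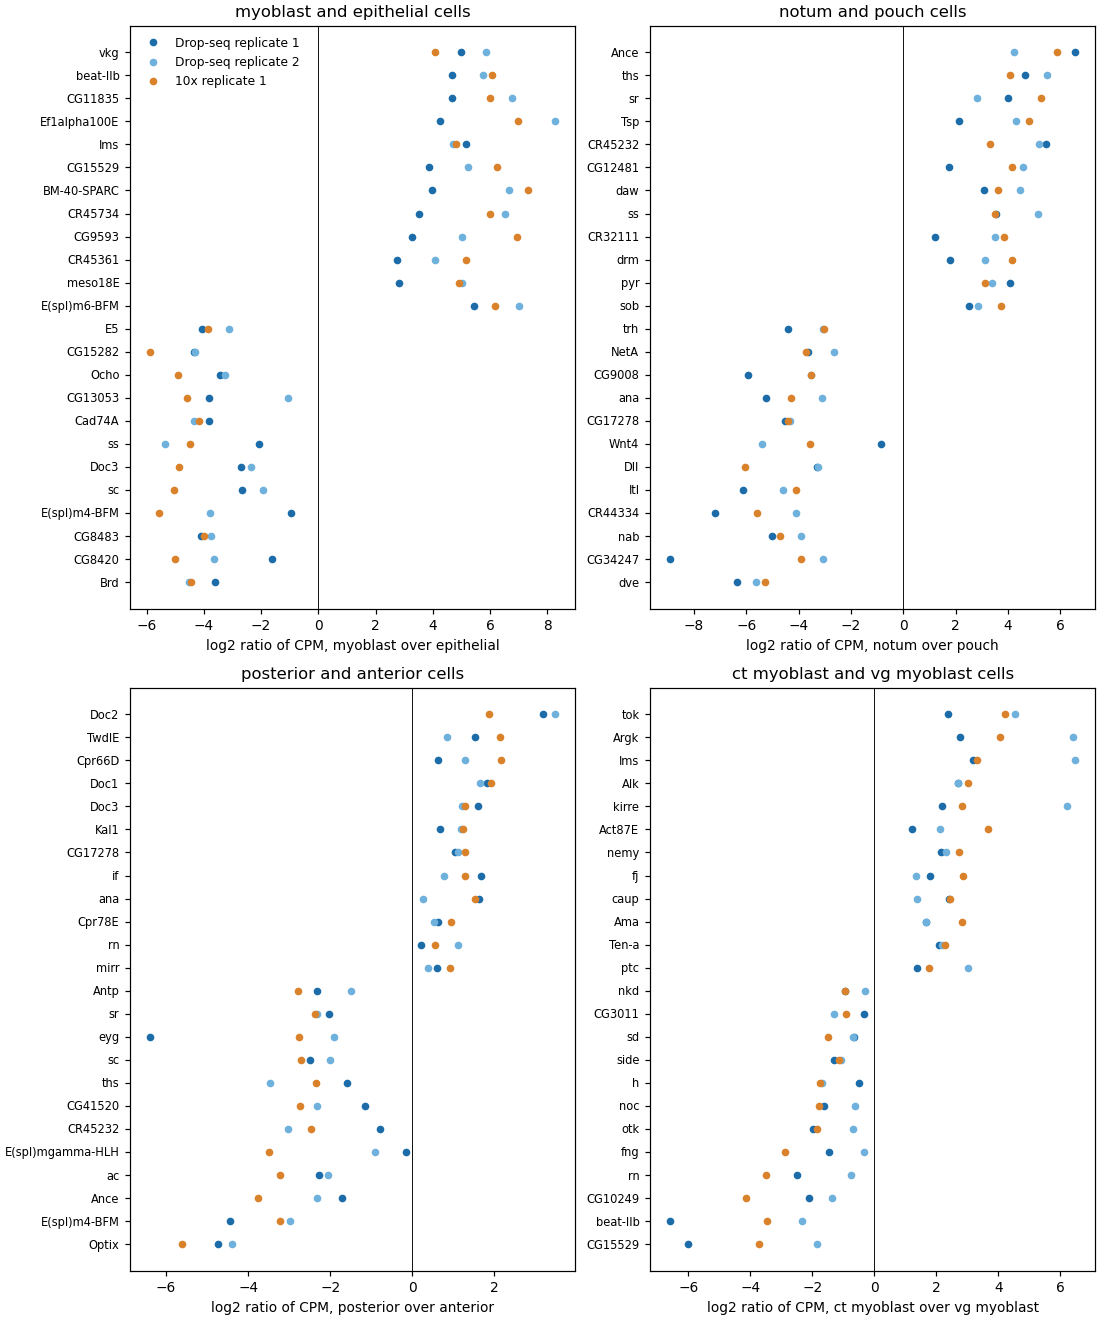
Difference in log2 CPM between the classes of each contrast (horizontal axis) for the 24 genes with the largest fitted differences, with 1 point per sample. The points of the 3 samples lie on the same side of 0 for each gene shown.

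The contrast of notum with pouch cells asked how epithelial cells of the future thorax differ from those of the future wing blade. Cells were assigned by the notum markers eyg, toe, tup, pnr and mirr or the pouch markers nub, pdm2, vg and rn, which were left out of the test. Of the notum markers mirr had the most counts, 652, 1442 and 2467 in the 3 samples, and 1 UMI of it was enough. In Drop-seq replicate 2, clusters of 134 and 123 cells were led by mirr among others and had the hinge markers zfh2, Sox15 and Dr. Neither had eyg, toe, tup or pnr among its markers, so the notum class can hold hinge cells. Of the pouch markers vg had the most counts, 949, 1415 and 12694 in the 3 samples, and 1 UMI of it was also enough. vg was among the markers of myoblast-like clusters in Drop-seq replicate 1 and 10x. Free RNA of myoblasts can thus put a cell in the pouch class. Ance, which encodes an angiotensin-converting enzyme homologue (2L, 13905645 to 13909212), was at 823 ± 335 CPM in notum cells and 16.9 ± 8.85 in pouch cells, a log2 difference of 5.48 (SE 0.232, adjusted p = 3.79e-10; 4.81 without the 10x sample). The FGF ligand genes ths and pyr, whose receptor htl is a myoblast gene, differed by 5.15 and 3.76. The tendon precursor gene sr differed by 5.08, or 3.38 without the 10x sample and 6.69 without Drop-seq replicate 2. The activin ligand gene daw differed by 4.52 and the transcription factor gene ss by 4.01 (not tested without the 10x sample), and the odd-skipped family genes drm and sob by 3.82 and 3.68. Tsp (thrombospondin), CR45232, CG12481 and CR32111 differed by 4.88, 4.82, 4.67 and 3.92. All were higher in notum cells in 3 of 3 samples, as the naming rule required. With 1 sample left out the log2 difference ranged from 3.90 to 5.19 for Tsp, 4.14 to 5.57 for CR45232, 3.30 to 4.09 for CR32111, 3.05 to 4.55 for drm and 2.96 to 4.002 for sob, and each still passed.

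Pouch cells had the homeobox gene dve (2R, 22243963 to 22286469) at 76.6 ± 23.5 CPM, with 464 counts against 2 in notum cells, a ratio of 123 (counting interval 33.8 to 1017). nab, a transcriptional cofactor gene, had 267 counts against 3, a ratio of 47.1 (15.9 to 229.9), and CG34247 had 298 against 2, a ratio of 78.9 (21.6 to 654), with 477 CPM in pouch cells of Drop-seq replicate 1 and 16.0 and 19.0 CPM in the other samples. The homeobox gene Dll was at 109 ± 18 CPM in pouch cells and 7.68 ± 6.4 in notum cells, a log2 difference of -4.76, which was -3.34 without the 10x sample and -6.96 without Drop-seq replicate 2. CG17278 was at 1010.1 ± 490.0 against 46.4 ± 23.9 CPM, a log2 difference of -4.41 (SE 0.11, adjusted p = 2.26e-13). ltl, Wnt4 and the netrin gene NetA differed by -5.31, -4.69 and -3.90, and CR44334, ana, CG9008 and trh by -5.35, -4.37, -4.04 and -3.80. All were lower in notum cells in 3 of 3 samples, as the naming rule required. With 1 sample left out the log2 difference ranged from -6.48 to -4.42 for nab, -6.53 to -5.05 for CG34247, -6.27 to -4.39 for CR44334, -5.96 to -5.02 for ltl, -5.12 to -4.04 for Wnt4, -6.09 to -3.40 for ana, -4.87 to -3.89 for NetA and -4.78 to -3.37 for trh, and each still passed where it was tested. NetA was not tested without the 10x sample.

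Most proximal wing and Iroquois genes were higher in notum cells, and 5 of 9 Wg pathway genes were higher in pouch cells. As the notum class can hold hinge cells, the rise of proximal wing genes cannot be assigned to the notum itself. Of 7 proximal wing and Iroquois genes 5 were higher and 0 lower, or 7 and 0 adjusted over the list alone, with a median of 1.21 (adjusted p = 2.7e-16; adjusted p = 0.584 with an estimated correlation). The Iroquois genes caup and ara differed by 2.47 (SE 0.156, adjusted p = 3.25e-08) and 1.62, and the zinc finger gene tsh by 2.44. Of the Wg pathway genes 5 were lower in notum cells, or 7 lower and 1 higher adjusted over the list alone, with a median of -0.84 (adjusted p = 4.92e-09; adjusted p = 0.584 with an estimated correlation). nkd, a feedback inhibitor, differed by -0.84. Of 12 glycolysis genes 3 were lower, or 7 adjusted over the list alone, with a median of -0.31 (adjusted p = 2.87e-06; adjusted p = 0.584 with an estimated correlation). ImpL3, at -0.997, lost its call without the 10x sample (-0.49), and Pglym78 (-0.59) and Pfk (-0.66) lost theirs whichever sample was left out, at -0.57, -0.70 and -0.50 and at -0.65, -0.87 and -0.37. Of 10 ecdysone genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.00656; adjusted p = 0.584 with an estimated correlation), among them ImpL2, an inhibitor of insulin signalling, at 2.07.

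Of 8 immediate early and JNK genes 3 were higher in notum cells (median 0.18, adjusted p = 0.0326; adjusted p = 0.584 with an estimated correlation): sr, and kay and puc at 0.87 and 0.58, which did not have this direction in all samples and lost their calls without the 10x sample, at 0.61 and 0.45, and without Drop-seq replicate 2, at 0.77 and 0.51. Of 9 E(spl) complex genes 4 were lower in notum cells (median -0.23, adjusted p = 0.00998; adjusted p = 0.758 with an estimated correlation), and this list rested on the 10x sample. Without it E(spl)m8-HLH (3 of 3 samples lower) went from -1.41 to -0.32, E(spl)m4-BFM from -1.71 to 0.13, E(spl)mgamma-HLH from -2.08 to 0.74 and the list median to 0.09, while without Drop-seq replicate 2 these genes were at -2.06, -2.57 and -3.03. The 3 calls also ended without Drop-seq replicate 1, at -1.41, -1.72 and -2.08. None of 83 ribosomal protein genes passed, while the list had a median of -0.08 (adjusted p = 4.63e-08; adjusted p = 0.758 with an estimated correlation). Single genes passed in other lists: bi, a Dpp target, at -0.91, the EGFR ligand gene vn at 1.35 and kek1 at 0.69, the protocadherin ds at 0.78, ft at 0.59 and the Golgi kinase gene fj at -1.39, and the transcription factor gene kn, which the Hh and direct flight muscle lists share, at -3.66. Camera adjusted p was 0.410 for the Dpp, 0.164 for the EGFR, 0.431 for the Fat and Dachsous, 0.492 for the Hh and 0.164 for the direct flight muscle list. The calls of ds (0.77), kek1 (0.68) and ft (0.45) ended without Drop-seq replicate 2, and that of ft also without the 10x sample (0.63).

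The polarity gene sdt (0.60) of 9 apical polarity genes, sls (-1.16) of 8 muscle genes and Hsp67Bc (-0.70) of 14 heat shock genes passed, and these calls were weak. That of sdt ended whichever sample was left out (0.59, 0.48 and 0.71), that of sls without either Drop-seq replicate (-1.10 and -1.04) and that of Hsp67Bc without Drop-seq replicate 1 (-0.75) and without the 10x sample (-0.09) (list adjusted p = 0.348, 0.670 and 0.818). No member passed of the 14 mitochondrial, 2 histone, 16 G2/M, 15 DNA replication, 5 basement membrane, 13 septate junction and 4 JAK/STAT genes, whose camera adjusted p ran from 0.0663 to 0.818. Median and mean had opposite signs in the EGFR list (-0.01 and 0.09) and, with no call, in the heat shock, mitochondrial, basement membrane, muscle, Dpp and Hh lists. In all, 232 of 5809 genes differed, 122 higher in notum cells and 110 higher in pouch cells. The count was 195 without Drop-seq replicate 1, 180 without Drop-seq replicate 2 and 133 without the 10x sample, and 121 with DESeq2.

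The contrast of posterior with anterior cells asked how the compartments of the disc differ. Cells were assigned by en, inv and hh or by ci, which were left out of the test. The classes were not matched for region of the disc. Ance, ths, sr and CR45232 were higher both in notum and in anterior cells, and CG17278 and ana both in pouch and in posterior cells. E(spl)m4-BFM, E(spl)mgamma-HLH and ImpL3 went the other way, higher in pouch and in anterior cells. Differences of compartment and of region cannot be told apart here. The T-box genes Doc2, Doc1 and Doc3, which lie in 1 cluster on 3L, were higher in posterior cells by 2.25 (SE 0.248, adjusted p = 1.55e-06), 1.93 (SE 0.159, adjusted p = 1.51e-08) and 1.33. Doc2 was at 40.7 ± 13.7 against 5.43 ± 3.92 CPM, and its log2 difference was 3.81 without the 10x sample, where Doc3 lost its call at 1.40. The cuticle genes TwdlE, Cpr66D and Cpr78E differed by 2.09, 1.94 and 0.85, and without the 10x sample Cpr66D was at 1.15 and Cpr78E lost its call at 0.56, while TwdlE was not tested. Kal1 (anosmin), the integrin gene if and the Iroquois gene mirr differed by 1.23, 1.22 and 0.71, and without the 10x sample their calls ended at 1.14, 1.05 and 0.44. CG17278, ana and rn differed by 1.22, 1.09 and 0.72, and the call of ana ended without Drop-seq replicate 2 (1.66) and without the 10x sample (0.49), and that of rn without Drop-seq replicate 2 (0.47). All were higher in posterior cells in 3 of 3 samples, as the naming rule required.

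Anterior cells had 281 counts of Optix, a sine oculis type homeobox gene (2R, 8031283 to 8042529), and posterior cells 0, at least 92.4-fold lower against a floor of 3 counts over the class, and it passed with each sample left out. Ance was at 275 ± 110 CPM in anterior cells and 44 ± 14.7 in posterior cells, a log2 difference of -3.26 (SE 0.188, adjusted p = 4.97e-11; -2.23 without the 10x sample). The proneural genes ac and sc were lower in posterior cells by -3.19 (-2.25 without the 10x sample) and -2.74, E(spl)m4-BFM by -3.34, and the notum genes eyg and ths by -2.71 and -2.84. sr differed by -2.68, the Hox gene Antp by -2.41 (-1.67 without the 10x sample), and CR45232 and CG41520 by -3.06 and -2.86, the latter by -2.25 without the 10x sample, where CR45232 was not tested. E(spl)mgamma-HLH, at -3.11, lost its call without the 10x sample, at -0.75. All were lower in posterior cells in 3 of 3 samples, as the naming rule required.

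Of 10 E(spl) complex genes, targets of Notch signalling, 6 were lower in posterior cells, or 9 adjusted over the list alone, with a median of -0.69 (adjusted p = 1.15e-19; adjusted p = 0.629 with an estimated correlation). E(spl)m7-HLH differed by -0.76, or -0.53 with no call without the 10x sample. Of 9 muscle differentiation genes 4 were lower, or 4 lower and 1 higher adjusted over the list alone (median -0.18, adjusted p = 2.1e-05; adjusted p = 0.629 with an estimated correlation). These were led by the adhesion genes rst at -2.36 (SE 0.184, adjusted p = 7.42e-09) and kirre at -1.30, which also act in epithelia. rst (X, 2950399 to 2973834) lies inside kirre on the opposite strand, and the strand setting of the counting was not given in the sources used here, so the pair is uncertain. kirre lost its call without Drop-seq replicate 2 (-1.22) and without the 10x sample (-1.18). Of 15 DNA replication genes 1, PCNA at 0.30, was higher in posterior cells, or 2 adjusted over the list alone (median 0.30, adjusted p = 0.000502; adjusted p = 0.629 with an estimated correlation). Of 16 G2/M genes 1 was higher, the Cdc25 gene stg at 0.59, not in all samples (list median 0.10, adjusted p = 0.0192; adjusted p = 0.629 with an estimated correlation). The calls of PCNA and stg ended without Drop-seq replicate 2, at 0.31 and 0.47, and without the 10x sample, at 0.36 and 0.43.

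Of 12 glycolysis genes 1, ImpL3 at -0.56, was lower (list median -0.12, adjusted p = 0.0135; adjusted p = 0.629 with an estimated correlation). Of 83 ribosomal protein genes 1, RpS3A at -0.20, was lower (list median -0.08, adjusted p = 1.89e-13; adjusted p = 0.629 with an estimated correlation). Both single calls ended without Drop-seq replicate 2, at -0.54 and -0.18, and without the 10x sample, at -0.83 and -0.18. In lists with no camera call, the Dpp feedback gene magu differed by -0.95, the Wg ligand gene wg by -0.73, Mkp3 and sty of the EGFR list by 0.40 and -0.53, Dr by -1.16, zfh2 by 0.62, kn by 2.23, and ImpL2 and ImpE2 by -0.94 and 0.20. wg, zfh2 and kn did not have this direction in all samples. Without Drop-seq replicate 2 every one of these calls ended, at -0.98, -0.63, 0.40, -0.35, -0.94, 0.36, 2.34, -0.74 and 0.21 in the same order. Without the 10x sample kn was at 1.28 and ImpL2 at -1.75. Adjusted over the list alone, 2 Dpp genes were lower, 1 Wg gene was higher and 2 lower, 1 EGFR gene higher and 2 lower, and 2 proximal wing genes higher and 2 lower. Camera adjusted p was 0.133 (Dpp), 0.308 (Wg), 0.998 (EGFR), 0.308 (proximal wing), 0.425 (Hh and also immediate early), 0.0922 (ecdysone) and 0.833 (direct flight muscle). The Hh target dpp was at 38.5 ± 44.7 CPM in posterior and 29.8 ± 21.7 in anterior cells, and its fitted log2 difference of -0.41 did not pass (adjusted p = 0.882). The means and the fit had opposite signs for dpp, as posterior cells were at 89.0 against 51.5 CPM in Drop-seq replicate 1, but at 22.5 against 29.8 in Drop-seq replicate 2 and 4.04 against 8.15 in 10x. No member passed of the 14 heat shock, 13 mitochondrial, 2 histone, 6 basement membrane, 13 septate junction, 9 apical polarity, 5 Fat and Dachsous and 4 JAK/STAT genes, whose adjusted p ran from 0.173 to 0.954.

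In all, 143 of 5899 genes differed, 33 higher in posterior cells and 110 higher in anterior cells. The count was 276 without Drop-seq replicate 1, 63 without Drop-seq replicate 2, 42 without the 10x sample and 37 with DESeq2. Of the named calls, 17 of 41 ended without Drop-seq replicate 2 and 20 of 39 without the 10x sample. Median, mean and camera direction differed in sign, with no call, in the immediate early, mitochondrial, histone, basement membrane, septate junction, Wg, EGFR, Hh and direct flight muscle lists.

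Within the myoblasts, cells with ct and without vg were set against cells with vg and without ct, which mark precursors of the direct and of the indirect flight muscles. tok, a tolloid-like metalloprotease gene (3R, 24719697 to 24749125), was at 145 ± 34.1 CPM in ct myoblasts and 11.6 ± 8.3 in vg myoblasts, a log2 difference of 4.10 (SE 0.348, adjusted p = 4.25e-05; 3.08 without the 10x sample). The arginine kinase gene Argk was at 1352 ± 535 against 80.3 ± 56.1 CPM, a difference of 3.99 (4.66 without Drop-seq replicate 1). The homeobox gene lms differed by 3.46, the receptor tyrosine kinase gene Alk by 3.08, the fusion receptor gene kirre by 3.06 and Act87E by 2.99, which was 1.66 without the 10x sample. As kirre overlaps rst on the opposite strand, its value is uncertain here too. nemy, the immunoglobulin gene Ama, the teneurin gene Ten-a and the Hh receptor gene ptc differed by 2.65, 2.32, 2.21 and 1.95, with Ama at 1.66 without the 10x sample. fj and caup differed by 2.50 and 2.36, and their calls, with that of kirre, ended without the 10x sample, at 1.66, 1.91 and 3.05. All were higher in ct myoblasts in 3 of 3 samples, as the naming rule required.

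The vg myoblasts had the higher level of beat-IIb, at 92.2 ± 12.9 against 8.56 ± 9.98 CPM, a log2 difference of -3.51 (SE 0.429, adjusted p = 0.000494). CG15529 and CG10249 differed by -3.57 and -3.15, the Fringe glycosyltransferase gene fng by -1.997, and rn by -2.10, and without the 10x sample these calls ended at -2.71, -1.83, -0.92 and -1.46. Without Drop-seq replicate 2 rn was at -3.20. sd, which encodes the DNA-binding partner of Vg, differed by -1.04, or -0.67 with no call without the 10x sample. otk, noc, h, side, CG3011 and nkd differed by between -1.52 and -0.81. Of these, noc kept its call with each sample left out, otk lost it without the 10x sample (-1.28), h, CG3011 and nkd in 2 of the 3 cases (lowest to highest -1.80 to -1.07, -1.04 to -0.78 and -0.98 to -0.70) and side in all 3 (-1.25 to -1.15). All were lower in ct myoblasts in 3 of 3 samples, as the naming rule required.

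Both tested direct flight muscle genes, lms and the LIM homeobox gene ap (1.86, or 2.06 with no call without the 10x sample), were higher in ct myoblasts (median 2.66, adjusted p = 4.07e-13; adjusted p = 0.465 with an estimated correlation). Of 7 muscle differentiation genes 3 were higher and 0 lower, kirre (uncertain, as above), Act87E and the actin gene Act57B at 1.90, which lost its call without the 10x sample at 0.90 (list median 0.36, adjusted p = 4.55e-06; adjusted p = 0.465 with an estimated correlation). Of 5 EGFR pathway genes 2 were higher, or 5 adjusted over the list alone, with a median of 0.91 (adjusted p = 2.03e-09; adjusted p = 0.465 with an estimated correlation), among them the feedback genes sty at 1.78 (SE 0.218, adjusted p = 0.000494) and kek1 at 1.54, which lost its call without the 10x sample at 1.32. Of 2 Hh pathway genes ptc was higher (median 0.96, adjusted p = 0.00823; adjusted p = 0.465 with an estimated correlation). Of 6 E(spl) complex genes 1, E(spl)malpha-BFM at 1.22, was higher (median 0.23, adjusted p = 0.00238; adjusted p = 0.485 with an estimated correlation).

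Of 83 ribosomal protein genes 6 were lower in ct myoblasts, or 52 adjusted over the list alone, with a median of -0.12 (adjusted p = 1.12e-12; adjusted p = 0.485 with an estimated correlation), for example RpS2 at -0.20, whose call ended without Drop-seq replicate 2 and without the 10x sample, at -0.24 and -0.18. Of 8 basement membrane genes 1, the collagen IV gene Cg25C at 1.37, was higher, or 4 adjusted over the list alone (median 0.60, adjusted p = 0.0494; adjusted p = 0.547 with an estimated correlation), and Cg25C lost its call without the 10x sample, at 0.73. The list median turned to -0.16 with 1 more UMI required in the class rule and to -0.05 with cells thinned to 1000 UMIs. Of 3 immediate early genes 1, kay at 1.35, was higher, or 3 adjusted over the list alone (median 0.78, adjusted p = 0.0494; adjusted p = 0.547 with an estimated correlation), with no call without the 10x sample (0.67) or without Drop-seq replicate 2 (1.49). In other lists brk (1.87, or 1.82 with no call without Drop-seq replicate 2) of 5 Dpp genes was higher (adjusted p = 0.0867), fz2 (1.14) was higher and nkd lower of 3 Wg genes (adjusted p = 0.880), caup was higher of 3 proximal wing genes (adjusted p = 0.142), and fj was the 1 Fat and Dachsous gene tested. None passed of the 14 heat shock, 13 mitochondrial, 12 G2/M, 9 DNA replication, 4 septate junction, 5 apical polarity, 10 glycolysis, 3 JAK/STAT and 5 ecdysone genes, whose adjusted p ran from 0.144 to 0.646. Adjusted over the list alone, 1 apical polarity, 1 JAK/STAT and 1 ecdysone gene were higher.

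In all, 80 of 2544 genes differed, 49 higher in ct and 31 higher in vg myoblasts, a higher share of 61.3%, which was 73.6% with library totals (64 and 23 genes) and 78.7% with DESeq2 (37 and 10 genes). The count was 144 without Drop-seq replicate 1, 66 without Drop-seq replicate 2, 33 without the 10x sample and 127 without cells with 3 or more roX1 UMIs. Of the 36 named calls, 21 ended without the 10x sample. Without the sample as a block, 369, 2, 0 and 0 genes passed in the myoblast, notum, posterior and ct contrasts, and with cells thinned to 1000 UMIs 1047, 34, 7 and 9. The classes held 40, 49 and 99 ct cells and 72, 45 and 886 vg cells in the 3 samples.

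Correlations of marker genes across cells asked whether genes known to share or exclude a domain do so in these cells. The posterior genes en and inv had a mean Pearson correlation of 0.379 ± 0.132 (SD, n = 3), and en and hh of 0.335 ± 0.105, both at or above the 99.98 percentile of random gene pairs matched on detection in each sample. en and the anterior gene ci had -0.142 ± 0.0497, at or below the 0.6 percentile. The myoblast genes twi and Him had 0.523 ± 0.134 and Him and zfh1 0.440 ± 0.0466, while Him and the epithelial gene grh had -0.475 ± 0.190. The pouch genes nub and vg had -0.0507 ± 0.104, nub and the notum gene eyg -0.0354 ± 0.0171, and the notum genes eyg and tup 0.0976 ± 0.102. By sample, nub and vg had -0.131, 0.0675 and -0.0891 and eyg and tup -0.0190, 0.140 and 0.172 in Drop-seq replicates 1 and 2 and 10x. The percentile of nub and vg ran from 0.25 to 75.7 and that of eyg and tup from 34.0 to 99.7 across the samples. Among cells with no myoblast UMI the correlation of nub and vg was -0.0352, 0.106 and 0.189 in the 3 samples, a mean of 0.0866, and vg is also a myoblast gene. Correlations across cells fell with depth: en and inv had 0.0796 at 1000 UMIs per cell.

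**Figure D4:**
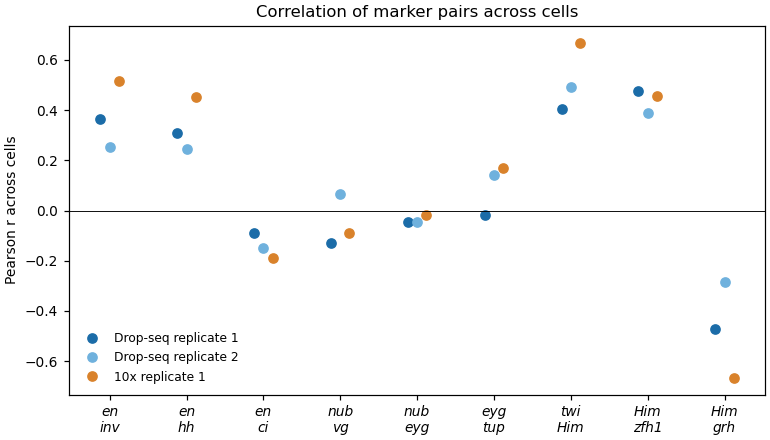
Pearson correlation across cells of log-scaled counts (vertical axis) for 9 pairs of marker genes, with 1 point for each of the 3 single-cell samples. The pairs en and inv, en and hh, twi and Him, and Him and zfh1 lie above 0 in all samples, en and ci and Him and grh lie below 0, and nub and vg and eyg and tup lie on both sides of 0.

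The bulk library was set beside the single-cell sums to ask how far the cells together resemble the whole tissue. Across 6275 genes with at least 10 CPM in bulk, the Pearson correlation of log2 CPM with bulk was 0.756, 0.774 and 0.623 for Drop-seq replicates 1 and 2 and 10x, and Spearman's rho was 0.714, 0.745 and 0.540. Genes are not independent replicates, so no p is given. The Drop-seq replicates had 0.978 with each other, and 0.868 and 0.885 with 10x. With no filter, over 17469 genes, the Pearson values were 0.907, 0.929 and 0.908. With bulk divided by transcript length, over the 5152 genes with a known length, they were 0.724, 0.756 and 0.778 and Spearman's rho 0.677, 0.728 and 0.753, so 10x went from the lowest value to the highest.

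Heat shock genes were the list farthest above bulk. 8 of 14 were at least 4-fold higher in every single-cell sample, with a median log2 ratio of 3.52, above all of 10000 random lists matched on level. Hsp68 (3R, 24055080 to 24057310) was at 4392 ± 1740 CPM (SD, n = 3) against 6.63 in bulk, a log2 ratio of 9.08 ± 0.65. The Hsp70 genes are near-identical copies, so single values are uncertain: Hsp70Bc was at 1851 ± 405 against 4.315 CPM, and Hsp70Ab at 2185 ± 2066 against 3.92, with 23.8 CPM in 10x. The 6 copies together had 6313, 9815 and 1638 CPM against 25.1. Heat shock genes took 6.10%, 6.39% and 4.70% of the single-cell counts and 1.18% of bulk counts. Ribosomal protein genes took 40.2%, 37.3% and 45.4% against 16.7%, with a median log2 ratio of 1.31 at the 65.3 percentile of matched lists and 4 genes, such as RpS9 at 2.79 ± 0.18, at least 4-fold higher. Mitochondrially encoded genes had a median of 0.09, with mt:ATPase6 at 3.53 and mt:lrRNA at -3.74 ± 0.45. E(spl) genes had a median of 1.68, led by E(spl)m6-BFM at 3.00 ± 0.74, and the myoblast markers a median of 0.98, led by Him at 3.57 ± 1.22. The myoblast median covered 4 markers and was 1.38, 0.108 and 1.44 in Drop-seq replicates 1 and 2 and 10x. The markers htl and stumps, below the level limit, had means of 21.6 and 16.1 CPM against 27.2 and 39.8 in bulk. These ratios were not corrected for transcript length, and of these lists only the heat shock list was checked for it.

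Septate junction and basement membrane genes were among the lists farthest below bulk, where the median of all genes was itself -1.10. The ratios of this paragraph were not corrected for transcript length. Over all genes 542 were at least 4-fold lower, and 78 with bulk divided by length, 65 of them shared. These low lists and genes may therefore owe to length. Of 13 septate junction genes 4 were at least 4-fold lower, with a median log2 ratio of -2.05 at the 0.06 percentile of matched lists, for example Cont at -3.50 and Mcr at -3.31. Of 6 basement membrane genes 2 were, with a median of -1.95 at the 1.76 percentile, LanA at -3.67 ± 0.14 and LanB2 at -2.94. Of 9 Hh pathway genes 4 were (median -1.80), for example ihog at -3.50, and of 6 Wg genes 2 were (median -1.55), the receptor genes arr at -2.79 and fz3 at -2.37. Of 9 muscle genes 2 were (median -1.50), Act87E at -4.38 ± 0.56 and mbc at -2.33, and ds (-2.95), tio (-3.32) and Patj (-2.93) were lower in lists with medians of -1.89, -1.90 and -1.25, the latter at the 22.65 percentile. No member was 4-fold apart in the immediate early (median -0.14), G2/M (-1.33), DNA replication (-1.54), glycolysis (-0.69), Dpp (-0.998), EGFR (0.02), JAK/STAT (-1.87) and ecdysone (-0.92) lists or for the direct flight muscle gene (-1.88). The marker lists had medians of -1.51 (epithelium), -0.995 (notum), -1.22 (pouch), -1.88 (hinge), 0.80 (peripodial), -1.56 (posterior), -2.11 (anterior) and -2.17 (trachea).

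By size, 55 genes were at least 4-fold higher and 542 at least 4-fold lower in all 3 single-cell samples, of 4018 genes with at least 50 CPM. The median log2 ratio over all of them was -1.10, and after centring on it 197 were higher and 114 lower. With bulk counts divided by transcript length, 79 were higher and 78 lower of 3310 genes. Of the genes named against bulk, 39 had a ratio that moved by more than the SD between samples when centred, and 28 when bulk was divided by length. Among the largest ratios, dUTPase had 557 ± 153 CPM and no bulk count, at least 9189.9-fold higher against 3 counts, CG3560 and Spase12 were at least 5207-fold and at least 2108-fold higher, and Nap1 stood at 705 ± 84.9 against 3.17 CPM. Below bulk, the ribosomal RNA pseudogene 28SrRNA-Psi:CR45851 had 0 counts against 99634, at least 41702-fold lower, and Prosalpha1 and CG30382 shared the bulk count 20893. Of the genes above bulk 32% overlapped another annotated gene on the same strand, of those below 10.5% and of the others 12.8%, and overlapping genes and copies are uncertain here.

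**Figure D5:**
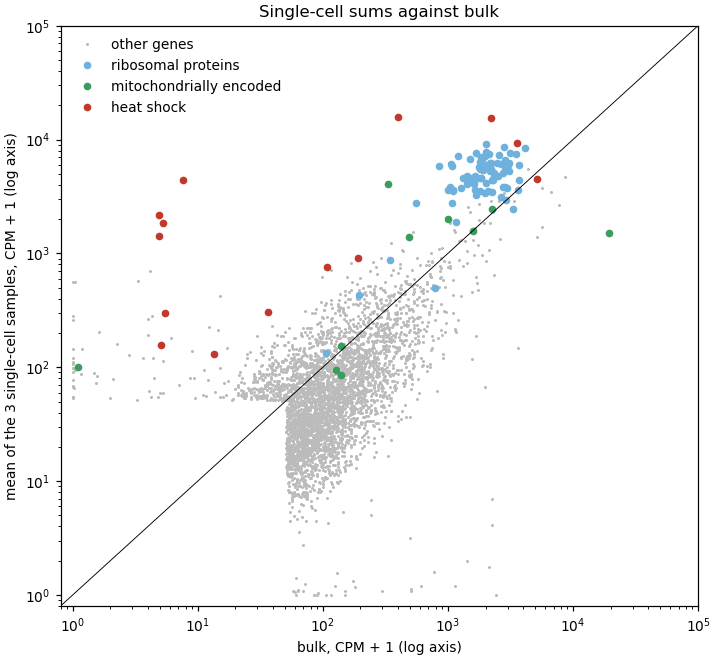
Mean CPM over the 3 single-cell samples against CPM in bulk, both as CPM + 1 on log scales, for genes with at least 50 CPM in either, with ribosomal protein, mitochondrially encoded and heat shock genes coloured. Most heat shock and ribosomal protein genes lie above the line of equal values, and 8 of 14 heat shock genes are at least 4-fold above bulk in every sample.

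Both Drop-seq replicates were set against 10x, which are different droplet methods and also different discs. Heat shock genes had a median log2 ratio of Drop-seq to 10x of 1.12, at the 99.9 percentile of matched lists, with 4 of 14 at least 4-fold higher in both replicates. All 4 were Hsp70 copies, whose single values are uncertain, such as Hsp70Bb at 448 ± 252 (SD, n = 2) against 1.32 CPM. The 6 copies together had 6313 and 9815 against 1638 CPM, which was under 4-fold in Drop-seq replicate 1. Epithelium markers had a median of 1.71 and myoblast markers of -1.44, at the 98.5 and 0.11 percentiles. The myoblast median covered 3 markers, Him at -1.53, twi at -1.44 and zfh1 at 0.04. The class shares of cells were counted from these same marker lists, so they are no separate evidence. The secreted morphogen gene dpp was at 87.5 and 34.4 CPM against 5.35, brk differed by 2.98 ± 0.55, the giant muscle scaffold gene Msp300 by 2.56 ± 0.57, zfh2 by 2.12 ± 0.09, ImpE1 by 2.11 ± 0.09 and sdt by 2.04. List medians were 1.41 for ecdysone, 1.27 for Dpp, 1.48 for muscle, 1.43 for Hh and 1.47 for proximal wing genes, and -0.58 for mitochondrial, -0.67 for glycolysis, -0.44 for E(spl) and -0.23 for ribosomal protein genes.

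Of 2752 genes with at least 50 CPM, 196 were at least 4-fold higher and 8 lower in Drop-seq. fabp, a fatty acid binding protein gene (3R, 11559896 to 11567054), had 0 Drop-seq counts and 21488 in 10x, at least 2190.3-fold lower, while sea stood at 307 ± 14.6 CPM in Drop-seq against 1 count in 10x. Both symbols have the same start, end and strand, so counts of this interval can go to either, and neither value is taken as a difference in expression. CR41597 had 0 Drop-seq counts and 2174 in 10x, at least 222-fold lower. Tsp42Ea, CG8501, CG40439, Uhg7, CG15529 and regucalcin were lower by log2 ratios from -4.03 to -2.52. Of these, CG8501 and regucalcin also led the haemocyte-like cluster of 10x, and CG15529 was higher in myoblasts, whose share was highest in 10x. Higher in Drop-seq, CG7215 stood at 388 ± 15.0 CPM against no 10x count, at least 5133-fold. CG43781, CG33995, CG42455 and CG17768 also had no 10x count. All 5 had no bulk count either, so these zeros are not taken as differences in expression between Drop-seq and 10x. Of the genes above 10x 28.99% overlapped another annotated gene on the same strand, against 12.8% of the others.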

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

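The tests of these values were chosen after the values were seen. Drop-seq replicate 2 library 2 had a median of 799 genes per cell, where the other Drop-seq libraries had 1203 to 1346. Its distance from the next library relative to the spread was 0.739, above the limit of 0.71 for 5 libraries. The same library had 41 barcodes that differed by 1 base from a larger barcode, where the others had 0 to 11, with a relative distance of 0.732. Such a rule picks about 1 in 20 groups by chance. Without such barcodes in any library the class contrasts gave 2533, 195, 156 and 80 genes. The bulk file held 2.04% of its counts under symbols that the single-cell files do not list, chiefly eEF1alpha1 with 546055 counts. Genes were matched by symbol, so a gene listed under different symbols counts as absent. Single-cell counts were left out in the same way. roX1 was at 10.2, 333 and 17.8 CPM over all genes of the 3 samples, and at 10.7, 348 and 18.8 CPM over the shared genes.

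The tests of roX RNA were chosen after the result was seen, except that of the cell classes. The pattern was a high level of roX1 and roX2 in Drop-seq replicate 2, whose discs were labelled female. Free RNA was argued against by the 82.1% of cells with no roX1 UMI, and cells of 1 type by the 9.20% of myoblasts and higher share of epithelial cells with 3 or more roX1 UMIs. Cells of male discs among the female ones could give such values, since 95.9% of roX2 UMIs lay in the cells with roX1. It stays open how such cells would have entered the sample, and X-linked counts were 17.7% of autosomal counts in cells with roX1 and 18.5% in cells without.

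The test of the summed Hsp70 copies was chosen after the result was seen, those of cell makeup and gene length before. The pattern was heat shock RNA above bulk in all single-cell samples. Cell makeup was argued against by a lowest class median of 2.34 and gene length by a lowest centred median of 3.47. Reads moved from 1 Hsp70 copy to another were argued against by a lowest log2 ratio of 5.97 for their sum. The sum cannot address reads dropped in bulk because they match more than 1 copy, as the counting tool was not given. A response to dissociation might still raise these RNAs, with the lowest class median of 2.34 left to explain, but the labels give 1 protocol for all samples, bulk included. No biological explanation was tested.

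The tests of depth and free RNA on the myoblast share were chosen after the result was seen, that of cells with roX1 before. The pattern was a lower share in Drop-seq replicate 2. Depth per cell was argued against by 8.11% after thinning, free myoblast RNA in the class rule by 21.3% of cells in myoblast-like clusters and cells with roX1 by 16.1% without them, each the lowest of the samples. Dissection or yield of dissociation could differ between replicates, which the value of 8.11% does not address. No biological explanation was tested.

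The splits of the class sums were chosen after the result was seen. In each contrast 1 of 10 splits, the real one, reached the number of genes found, and 10 splits are too few for a share under 0.05. The real and highest other values were 2563 and 0 for myoblasts and epithelium, 232 and 7 for notum and pouch, 143 and 113 for posterior and anterior, and 80 and 48 for ct and vg myoblasts. The value of 113 came from swapping the classes in Drop-seq replicate 1 alone, and that of 48 from splits that keep the sums of each Drop-seq replicate together and part only the 10x pair. The sums are paired by sample, and only 4 of the 10 splits, the real one among them, part every pair; the others leave at least 1 sample's sums on the same side and are no swaps of class labels. Among the splits that part every pair the highest other values were 0, 7, 113 and 0.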

How the results depend on the processing

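Settings that moved a result most are given here, and the cause was not tested unless stated. Without the block for the sample, edgeR found 369, 2, 0 and 0 genes in the myoblast, notum, posterior and ct contrasts, with raw p under 0.05 for 1067, 108, 47 and 37 genes, and DESeq2 with the block found 1912, 121, 37 and 47. With cells thinned to 1000 UMIs the contrasts gave 1047, 34, 7 and 9 genes, as fewer counts entered the sums. With no low-count filter they gave 2792, 364, 222 and 256. Without cells with 3 or more roX1 UMIs the ct contrast gave 127 genes.

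With 1 sample left out the number of genes ran from 1642 to 3434, 133 to 195, 42 to 276 and 33 to 144, lowest without 10x and highest without Drop-seq replicate 1 in each contrast. In the notum contrast E(spl)m4-BFM ran from -2.57 to 0.13 and E(spl)mgamma-HLH from -3.03 to 0.74. The gene lists called by camera in limma were 0, 0, 0 and 0 with an estimated correlation, against 14, 7, 6 and 8 with the preset one. With 3 samples hardly any list could pass with an estimated correlation, so the 0 calls do not decide on any list.

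With no filter the mean correlation of single-cell sums with bulk was 0.915 by Pearson and 0.869 by Spearman. The genes 4-fold apart from bulk were 311 with centred ratios, 155 at 200 CPM or more and 157 with bulk divided by length, and those between Drop-seq and 10x were 46 at 200 CPM or more. The mean myoblast share was 15.3% with cells thinned.

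With cells thinned the mean marker correlations were 0.0796 for en and inv, 0.0775 for en and hh, -0.0335 for en and ci, -0.00528 for nub and eyg, 0.208 for twi and Him, 0.103 for Him and zfh1 and -0.163 for Him and grh. Spearman's correlation gave 0.455 for en and hh and turned nub and eyg to 0.0220. In cells with 0 myoblast UMIs nub and vg had 0.0866 and nub and eyg -0.127.

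Library totals, 1 more UMI in the class rule, 500 genes per cell, all barcodes, no doublets, no barcodes 1 base apart and none over 50000 UMIs left every count of genes within 1.5 times its value. Over the single values, 398 lost their call, 48 gained one, 254 moved and 2 reversed. The other 5491 passed in both settings, passed in neither or, for values with no test, stayed near their size. So 5491 is not a count of kept calls. A kept call does not mean a kept fold: of the named myoblast genes, 30 folds moved by over 1.5 times without 10x and 17 without Drop-seq replicate 1.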

Other observations

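Some groups of cells stood apart that the contrasts did not ask about, and they were described after the clusters were seen. The 10x sample had a cluster of 20 cells, 0.783% (exact 95% interval 0.479 to 1.21), with all 6 haemocyte markers, led by CG8501, regucalcin and lectin-28C. Of these cells 14 met the myoblast rule, and without the cluster the myoblast contrast gave 2537 genes. No Drop-seq cluster carried this name, but the smallest clusters there held 47 and 9 cells, so this sets no limit on such cells. Hml was at 1.78, 0.264 and 0.862 CPM in Drop-seq replicates 1 and 2 and 10x. The other haemocyte markers were higher in 10x than in both Drop-seq replicates. In the same order He was at 0.667, 1.32 and 8.92 CPM, NimC1 at 0.667, 1.06 and 1.95 and srp at 0.444, 0.661 and 1.70. Nplp2 was at 0, 0.264 and 0.837 CPM and eater at 0.444, 1.06 and 1.90. The 10x sample also had 10 cells led by E(spl)mgamma-HLH, E(spl)m4-BFM, Ocho, Tom and Brd, with the proneural genes ac and sc, and 26 cells with sens and elav. The cluster of 26 cells also had E(spl)m4-BFM, E(spl)mgamma-HLH and Ocho among its leading genes. A cluster of 52 cells (2.04%) in 10x and 1 of 15 cells (1.37%) in Drop-seq replicate 2 were led by Idgf4 and Cpr49Ac, the former with the peripodial markers Ubx, Antp and puc and the tracheal markers kni, serp and verm, the latter with Ubx and the tracheal markers btl, kni, serp and verm, so neither was named by these. A cluster of 9 cells in Drop-seq replicate 2 was led by ImpL3, Ilp8, ImpL2 and Mmp1.

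Between the Drop-seq replicates 12 genes were at least 4-fold higher in replicate 1, and 8 of them were CR symbols (66.7%, against 0.951% of all genes at this level), such as CR31144 at 316 against 2.64 CPM. The 4 genes higher in replicate 2 were roX1, CR40469 at 2242 against 232 CPM, Cpr49Ac at 258 against 29.5 CPM and Phk-3 at 265 against 63.3 CPM. In the 2 libraries of replicate 2 Cpr49Ac stood at 97.2 and 495 CPM and CR40469 at 3501 and 395 CPM. The 4-fold size thus rests on 1 library for each, library 2 for Cpr49Ac and library 1 for CR40469. No test was made of these values.

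Some markers of other tissues were low. Hml was at 1.78, 0.264 and 0.862 CPM in the single-cell samples and 2.10 in bulk, Fbp1 at 2.67, 2.64 and 0.0254 against 1.34, and repo at 0.667, 0.397 and 0.228 against 0.317. The tracheal genes btl and trh were lower than in bulk, btl at 5.33, 0.793 and 0.558 against 12.3 CPM and trh at 16.0, 25.1 and 5.10 against 64.0. Other members of these marker lists were not low: verm was at 86.0, 163 and 116 CPM against 536, serp at 71.1, 93.1 and 30.1 against 213, and the neuronal gene elav at 58.9, 42.7 and 13.9 against 32.6. An unnamed cluster of 140 cells in Drop-seq replicate 2 had a median of 723.5 counts, and an unnamed cluster of 61 cells in 10x held markers of both myoblasts and epithelium. With clusters in place of marker rules, each made from 1 set of genes and tested on the other set, 2918 of 7349 genes differed between myoblast-like and epithelium-like cells.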
